A study of Mus musculus with 2 samples.

How the data were processed

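Single-cell RNA was measured in 1 dorsal and 1 ventral library from the base of the neonatal mouse heart. Per the labels' protocols, cells of 15 hearts from 3-day-old C57Bl6 mice of both sexes were combined into a dorsal and a ventral pool, kept in adherent culture for 5 days and released with trypsin. Libraries were made with 10x Genomics 3' chemistry. Per the submitters' processing notes, Cell Ranger 3.0.2 was run against mm10. The annotation release and alignment settings are not given in the sources used here. The matrices deposited by the authors hold raw UMI counts for 28692 genes and 6794880 barcodes per library, without normalisation and without selection of cells. Total UMIs were 246920028 in the dorsal and 264822916 in the ventral matrix. Gene IDs were matched to GENCODE M21 on GRCm38 for genome positions, and 28339 of the 28692 IDs matched.

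Cells were called in each library from the UMI totals. A barcode was kept when its total reached 10% of the 99th percentile of the 5000 highest totals, when it had at least 500 genes and when at most 20% of its UMIs were mitochondrial. The resulting UMI minimum was 8143 in the dorsal and 6613 in the ventral library. These steps left 8908 dorsal and 10761 ventral barcodes. Scrublet, as included in scanpy, was run per library with an expected doublet fraction of 0.008 for every 1000 cells. Its automatic threshold marked 8.17% of ventral barcodes, and these 879 were removed. In the dorsal library it marked 0.0112%, below the preset 0.5% at which the caller counted as failed, so the expected share with the highest scores was removed instead, which came to 635 barcodes or 7.13%.

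The remaining 8273 dorsal and 9882 ventral cells were normalised to 10000 UMIs per cell, log-transformed and clustered together without integration. The settings were 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0. The rule that turned clusters into cell classes was set after the clusters had been seen, with 20 marker lists written earlier. A cluster took the class with the largest fraction of markers detected in at least 25% of its cells and at least 2-fold higher than in the other cells, with 5 CPM added to both sides. At least 3 markers and 1/3 of the list were needed, and no other class could have more markers among the cluster's 10 leading genes. A cluster with no such class was called fibroblast-like when at least 5 fibroblast markers were found in at least 50% of its cells and fewer than 5 of its 10 leading genes were cell cycle genes, again only when no other class had more markers than fibroblasts among the 10. Clusters 0 and 3 failed this last condition, by the pericyte marker Ndufa4l2 and the chondrocyte marker Col9a1, and stayed unnamed. Smooth muscle and pericyte markers were pooled as mural. All other clusters stayed unnamed. Class names therefore describe marker patterns in cultured cells, and each carries the ending "-like".

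With 1 library per domain there were no replicates, so no test between domains was made and no p-value was computed from cells. Values are given for both libraries as CPM, the usual scaled fraction of all UMIs of the summed cells, or as shares of cells. Exact Poisson intervals were used for CPM, exact conditional binomial intervals for ratios of CPM, Clopper-Pearson intervals for shares, and a combination of the latter for ratios of shares. All are 95% intervals and cover counting error only. They do not cover differences between dissections, cultures or library preparations. A count of 0 was given an upper limit of 3 counts, and a fold against 0 was stated as a lower bound against that limit. Genes at 20 CPM or more in either library were counted by whether they differed at least 2-fold, as a description of size and not as a call.

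The named genes of the pooled comparison were the 12 with the highest and the 12 with the lowest ratio among genes at 20 CPM or more, leaving out mitochondrial, ribosomal protein and provisional gene names, together with Isl1 and up to 4 members of each list. Within a class, the 6 highest and the 6 lowest were named. For Isl1-positive cells, the 12 genes with the highest and the 6 with the lowest ratio in both libraries were named, and list members served as examples. Comparisons, alternatives, 26 gene lists and the naming of genes were fixed before the data were examined. A further 3 lists and several alternatives were added afterwards and are identified where they appear. For each list, the median log2 ratio over members with at least 50 UMIs was ranked among 10000 random lists of the same size whose members were matched on expression. The rank describes these 2 libraries and is not a test, since random members were drawn separately while list members can share the same cells. The same medians were also computed with every class found in both libraries held at its mean share, so that differences in class shares were removed. Skeletal muscle-like cells, found in 1 library, dropped out there, and the unnamed clusters other than the cycling one entered as 1 class. For medians within a class, list members needed at least 20 UMIs and UMIs in both libraries.

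To compare shares of cells with a UMI at equal depth, every cell was thinned at random to 10000 UMIs, which left out 328 dorsal and 348 ventral cells with fewer. A cell was counted as cycling when at least 3 UMIs fell on a list of 20 G2 and M phase genes after thinning. Alternatives changed 1 choice at a time, except that Scrublet was run again whenever the UMI minimum or the mitochondrial limit changed. They covered the UMI minimum, the mitochondrial limit, doublet removal, Leiden resolution, the number of variable genes, TMM scaling from edgeR, equal weight for each cell, subtraction of 10% free RNA profile, the expression minimum, thinning depth, a minimum of 5 UMIs for a cycling cell, class weights, the omission of muscle-like cells, classes with at least 25 cells and the naming of large unnamed clusters. The free RNA profile came from barcodes with at most 100 UMIs.

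The procedure was tested on simulated data with Poisson counting error only. Over 5414 genes in the pooled comparison, the intervals held the true ratio for 95.0% of 5214 unchanged genes. All 50 genes simulated at each of 2.5-, 4- and 8-fold came out at least 2-fold apart, and 0 of 50 simulated at 1.5-fold did. Of 200 unchanged lists, 188 ranked between the 2.5 and 97.5 percentiles, and 0 of 200 lists shifted by 0.5 did. These simulations hold no variation between animals or cultures, so they say nothing about it. Both simulated libraries shared 1 profile, so unchanged lists differed by counting error and the changed genes only. In the real data the upper 95% bound of matched random lists reached 0.55 for sinoatrial and 0.88 for autonomic neuron genes. A shift of 0.5 could therefore stay within the random range of real lists.

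Work was done with Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scikit-image 0.26.0, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16. Barcodes below the UMI minimum were left out of all comparisons. Splits of the samples could not be formed with 2 libraries. Values of some single genes that met the naming rule are not reported here.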

Results

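The study compared cells from the dorsal and the ventral side of the base of the neonatal mouse heart, and its title places Isl1-expressing neural crest cells of the inflow tract at its centre. Isl1 encodes a LIM-homeodomain transcription factor of cardiac progenitors, pacemaker tissue and several kinds of neuron. The dorsal dissection took in the sinoatrial node, the cardiac ganglia and the pulmonary veins. The ventral dissection took in the proximal aorta, the pulmonary artery and the base of the outflow tract. Each domain was measured in 1 library from a pool of 15 hearts after 5 days of culture, so there were no replicates. The dorsal library held 8273 called cells with 203868545 UMIs, 82.6% of its total, and a median of 21924 UMIs and 4432 genes per cell. The ventral library held 9882 cells with 222648985 UMIs, 84.1% of its total, and a median of 20732 UMIs and 4229 genes per cell. Mitochondrial genes took a median of 3.03% of UMIs in dorsal and 4.12% in ventral cells.

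The first comparison asked which cell classes each domain held. Schwann and glial-like cells, marked by Sox10 and Cdh19, made up 4.94% of dorsal cells (409 cells, 95% interval 4.49 to 5.43) and 1.69% of ventral cells (167 cells, 1.45 to 1.96), a 2.93-fold higher dorsal share. Macrophage-like cells made up 1.79% of dorsal (148 cells) and 1.0% of ventral cells (99 cells), a log2 ratio of 0.84 (0.47 to 1.21). Mural-like cells, with smooth muscle and pericyte markers, were less frequent in dorsal cells, at 6.82% against 12.7%, a log2 ratio of -0.90 (-1.04 to -0.76) that ran from -0.32 with a minimum of 2000 UMIs to -1.50 with 4000 variable genes. With 4000 variable genes the mural name also went to a cluster of 16 dorsal and 778 ventral cells led by cell cycle genes such as Ube2c and Top2a. Skeletal muscle-like cells with Myog, Acta1 and Mylpf were found in the dorsal library, at 35 cells or 0.423%. The ventral library had 0 of 9882 such cells, which allows a share of up to 0.0304%.

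Most cells of both libraries were mesenchymal. Fibroblast-like cells formed 45.9% of dorsal and 64.6% of ventral cells. A further 25% of dorsal and 0.850% of ventral cells lay in unnamed clusters. The largest of these, cluster 0 with 17.5% of dorsal cells and 17 ventral cells, was led by Sele, Cxcl2 and Fbln1. Cluster 3, with 7.07% of dorsal and 0 ventral cells, was led by Mmp13, Col10a1 and Mmp3. Both carried fibroblast markers in at least 50% of cells, 10 of the markers in cluster 0 and 7 in cluster 3. When these were counted as fibroblast-like, an alternative chosen after seeing the data, the shares were 70.5% and 64.7% and the direction of the difference turned over, from a log2 ratio of -0.49 to 0.12 (0.09 to 0.15). The dorsal to ventral ratio of fibroblast-like cells was therefore not settled by these data.

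Mesothelial-like cells, the lining cells of body cavities, formed 11.8% of dorsal and 9.63% of ventral cells, a log2 ratio of 0.30 that became -0.56 at Leiden resolution 2.0. Endothelial-like cells had similar shares of 1.18% (98 cells) and 1.31% (129 cells), a log2 ratio of -0.14 (-0.53 to 0.24). Cardiomyocyte-like cells were rare in both libraries, at 0.435% (36 cells) and 0.304% (30 cells), a log2 ratio of 0.52 (-0.21 to 1.25) that reached 1.41 with a mitochondrial limit of 10%. A cycling cluster without a class name, led by Ube2c, Top2a and Prc1, held 1.70% of dorsal and 7.91% of ventral cells. A small unnamed cluster of 27 dorsal and 7 ventral cells carried both S100a8 and S100a9, which are neutrophil genes, and the T cell receptor genes Cd3d and Cd3g.

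**Figure D1:**
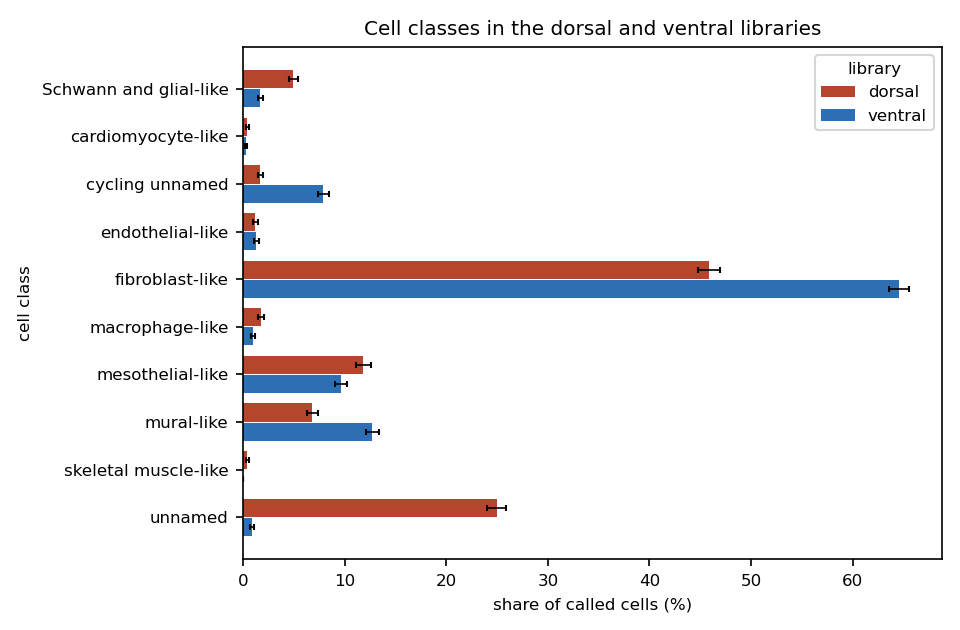
Share of called cells in each cell class (x axis, %) for the dorsal library of 8273 cells and the ventral library of 9882 cells, with bars for 95% Clopper-Pearson intervals (counting error only). Glial-like cells took 4.94% of dorsal and 1.69% of ventral cells, and unnamed clusters took 25% and 0.850%.

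Mesenchymal cells of the domains fell into different clusters. Of 25 clusters, 19 drew at least 90% of their cells from 1 library, and these held 16082 of 18155 cells (88.6%). Fibroblast-like cells came from clusters 1, 2 and 9 on the dorsal side and from clusters 16, 18, 19, 20 and 24 on the ventral side. Dorsal cluster 1 was led by Tnfsf8, Cxcl13 and Il33, dorsal cluster 2 by Gdf10, Cdo1 and Barx1, and dorsal cluster 9 by Grem1, Thbs4 and Chil1. Ventral cluster 16 was led by Gpx3, Adamtsl2 and Slc38a5, ventral cluster 18 by Fmod, Scx and Timp3, and ventral cluster 20 by Cd200, Cxcl12 and Angpt2. Glial-like, macrophage-like, endothelial-like and cardiomyocyte-like cells of both libraries shared 1 cluster for each class. At Leiden resolution 2.0 glial-like cells split into a cluster of 372 dorsal and 32 ventral cells and one of 37 dorsal and 135 ventral cells. A cluster drawn mostly from 1 library may stand for that library as well as for a cell type, since domain and library were the same split.

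The second comparison summed all cells of each library, gene by gene. The widest ratio was that of Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484), an arginase of activated macrophages, at 41.0 CPM in dorsal and 0.0269 CPM in ventral cells, a log2 ratio of 10.57 (9.45 to 12.02). Macrophage-like cells held 96.5% of its dorsal UMIs. The neutrophil chemokine Cxcl2 (ENSMUSG00000058427, chromosome 5, 90903871 to 90905938) stood at 812 against 30.8 CPM, a log2 ratio of 4.72 (4.69 to 4.76). On the ventral side, smooth muscle actin Acta2 (ENSMUSG00000035783, chromosome 19, 34241090 to 34255590) stood at 855 CPM in dorsal and 5847 CPM in ventral cells, a log2 ratio of -2.77 (-2.78 to -2.77).

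Other dorsal-high genes were Csf3 (log2 ratio 5.68), a neutrophil growth factor, Calca (5.41), which encodes calcitonin gene-related peptide, the BMP antagonist Grem1 (5.19, with 63.6 against 1.75 CPM) and the TNF family ligand Tnfsf8 (5.04). Skeletal muscle genes filled the remaining places, with Tnnc2 at 7.41, Acta1 at 6.98, Mylpf at 6.90, Myl1 at 6.35, Tnni2 at 6.28 and Tnnt3 at 6.25. Between 83.8% (Tnnt3) and 96.6% (Tnnc2) of their dorsal UMIs came from the 35 skeletal muscle-like cells. Without muscle-like cells, an alternative added after seeing the data, their log2 ratios were 2.55 for Tnnc2, 2.61 for Acta1, 2.14 for Mylpf, 4.43 for Myl1, 2.88 for Tnni2 and 3.58 for Tnnt3.

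Ventral-high genes included the chemokine Ccl17 (ENSMUSG00000031780, log2 ratio -4.71), the cartilage proteoglycan Acan (-4.64, with 1.23 against 30.7 CPM), the calcium-binding protein S100a4 (-3.69) and the microtubule protein Map2 (-3.46). Scel followed at -3.04, the uroplakins Upk1b at -3.01 and Upk3b at -2.94, and the peptide receptor subunit Ramp1 at -2.80. Map3k7cl stood at -2.62, the collagen Col8a1 at -2.61 (65.3 against 399 CPM) and the cardiac T-box factor Tbx20 at -2.56 (8.71 against 51.2 CPM). Of 5811 genes at 20 CPM or more, 276 were at least 2-fold higher in the dorsal and 295 at least 2-fold higher in the ventral library. TMM scaling moved the median log2 ratio of these genes from 0.01 to -0.12 and the counts to 243 and 355. Without the expression minimum the counts were 4445 and 2153.

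**Figure D2:**
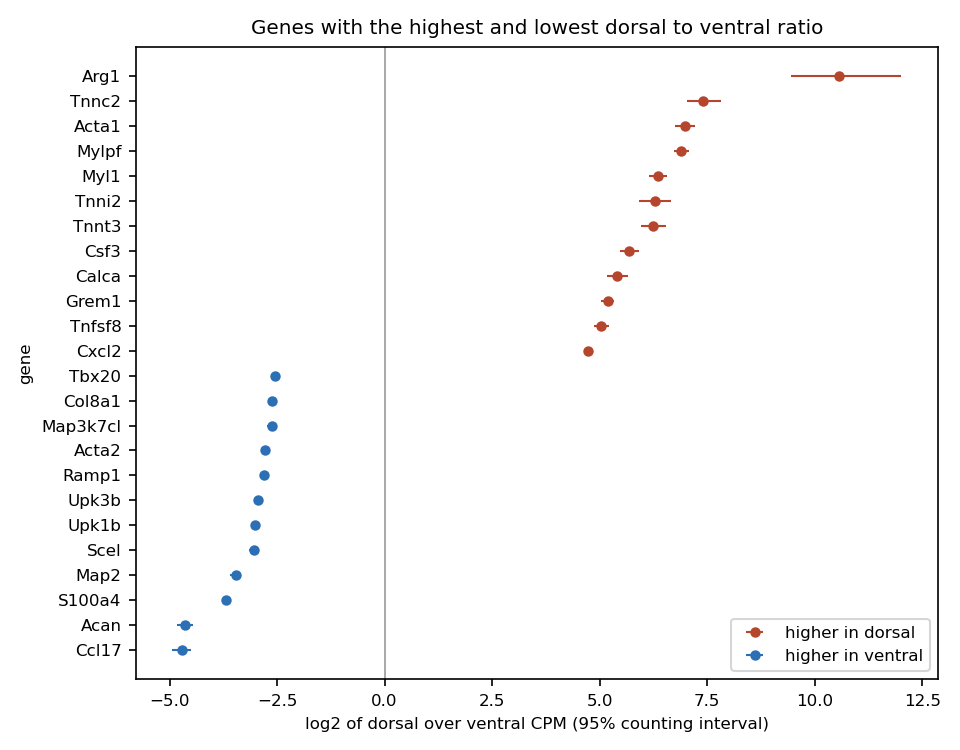
Log2 ratio of dorsal to ventral CPM (x axis) for the 12 genes with the highest and the 12 with the lowest ratio among genes at 20 CPM or more, with bars for 95% counting intervals. Arg1 stands highest at 10.57 and Ccl17 lowest at -4.71.

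Gene lists fixed in advance were then compared by the median log2 ratio of their members, and each median was ranked among matched random lists, as a description and not as a test. Neural crest regulators had a median of 0.50 at the 99.2 percentile, with 8 of 19 members at least 2-fold higher in dorsal and 2 in ventral cells. The dorsal-high members included Sox10 at 1.36, Foxd3 at 1.32, the neurotrophin receptor Ngfr at 1.57 and the endothelin receptors Ednrb at 2.13 and Ednra at 1.54. Glial-like cells held 95.9% of Sox10 UMIs, 96.3% of Foxd3 UMIs and 93.5% of Ngfr UMIs. Snai1 at -1.46 and Plxna2 at -1.34 were higher in ventral cells. With each class at its mean share the list median was -0.08.

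Schwann and satellite glia genes had a median of 1.32, with 8 of 14 members at least 2-fold higher in dorsal cells and 0 in ventral cells. Examples were Gfra3 at 3.08, Sostdc1 at 3.20, Gap43 at 2.30 and Erbb3 at 1.80, whereas Mbp stood at -0.05 and S100b at 0.03. Their median was 0.14 with each class at its mean share. Autonomic neuron genes had a median of 0.24 at the 48.1 percentile. Among 12 measured members, Phox2a at 2.24, Gap43 and Gata2 at 1.08 were at least 2-fold higher in dorsal cells, and Hand2 at -1.74 and Dbh at -2.86 in ventral cells.

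Sinoatrial node and pacemaker genes had a median of 0.85 at the 99.8 percentile, and of 0.62 with each class at its mean share. Of 15 members, 6 were at least 2-fold higher in dorsal cells, among them the T-box repressor Tbx3 at 2.45, the calcium channel genes Cacna1d at 2.28 and Cacna1g at 2.19, and Cpne5 at 2.67. Fibroblast-like cells held 58.5% of Tbx3 UMIs and 59.5% of Cacna1g UMIs. The pacemaker channel gene Hcn4 was near the floor at 0.22 and 0.12 CPM, Shox2 stood at 0.79, and Bmp4 was higher in ventral cells at -1.61. Inflow and pulmonary vein genes had a median of 1.17 at the 99.99 percentile, with 6 of 12 members at least 2-fold higher in dorsal and 0 in ventral cells. Examples were Tbx4 at 5.31, Gli1 at 4.19, Foxf1 at 2.96, Tbx5 at 2.69 and Hoxa5 at 1.43. Tbx4 is also taken below as a gene of airway and foregut mesenchyme. At Leiden resolution 2.0, Tbx4, Foxf1 and Barx1 were among the leading genes of a fibroblast-like cluster of 1161 dorsal and 0 ventral cells. The list therefore does not tell inflow tissue from airway or foregut mesenchyme.

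Second heart field and outflow genes had a median of -0.52, lower than in all 10000 random lists. The cardiac factors Hand1 at -6.44, Tbx20 at -2.56, Hand2 at -1.74, Nkx2-5 at -1.46 and Gata4 at -1.09 were higher in ventral cells. Tbx1 at 2.60, Fgf10 at 2.52 and Sema3c at 1.03 were higher in dorsal cells. Anterior Hox genes had a median of 0.04 that became -0.07 with TMM scaling, and Hoxa5 was at least 2-fold higher in dorsal cells.

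Muscle genes of the chambers divided by domain. Atrial muscle genes had a median of 1.06, with 5 of 9 members at least 2-fold higher in dorsal cells, among them Nppa at 3.91, Myl4 at 2.84, Sln at 2.54 and Myl7 at 2.10. Cardiomyocyte-like cells held 95.4% of dorsal Nppa UMIs, and the median was -0.04 without muscle-like cells. Ventricular muscle genes had a median of -1.91, with 5 of 8 members at least 2-fold higher in ventral and 0 in dorsal cells, including Myl2 at -5.40 and Myl3 at -3.88. In the ventral library 89.5% of Myl2 UMIs and 92.2% of Myl3 UMIs came from the 30 cardiomyocyte-like cells.

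Smooth muscle contractile genes had a median of -1.03, with Acta2, Tagln at -2.24, Myocd at -2.06, Lmod1 at -1.69, Itga8 at -1.34 and Cnn1 at -1.30 at least 2-fold higher in ventral cells and Des at 2.67 in dorsal cells. With each class at its mean share the median was -0.33. Of 12 arterial wall and elastic fibre genes, Eln at -1.45 (2911 against 7937 CPM) and Fbln5 at -2.0 were at least 2-fold higher in ventral cells, and 10 were within 2-fold. The list median of -0.32 lay within the middle 95% of random lists, at the 4.63 percentile. Myofibroblast activation genes had a median of -0.36 at the 2.86 percentile, also within that range, with 3 of 11 members at least 2-fold higher in ventral cells, Acta2, Tagln and Ctgf at -1.20, while Postn at -0.08 and Col1a1 at 0.19 were close to equal. Valve and chondrogenic genes divided 3 to 3 with a median of -0.36. The cartilage collagen Col2a1 at 5.55, with 90.9% of its UMIs in unnamed clusters, Nfatc1 at 1.98 and Vcan at 1.93 were higher in dorsal cells, and Acan, Scx at -2.24 and Tnmd at -1.88 in ventral cells.

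Among signalling lists, Notch genes had a median of -1.18, lower than in all random lists. Of 11 members 6 were at least 2-fold higher in ventral cells, including Hey2 at -2.17, Heyl at -1.98, Hes1 at -1.70 and Notch3 at -1.67, whereas Dll1 stood at 1.35 and Notch1 at 0.00. BMP ligands, antagonists and targets had a median of 0.04, which was -0.08 with TMM scaling, and moved in both directions. Of 16 members, 7 were at least 2-fold higher in dorsal cells, among them 3 ligands and the antagonists Grem1 at 5.19 and Chrdl1 at 3.85, while the ligands Bmp4 and Bmp6 (-1.97) and the target genes Id1 at -1.58 and Smad6 at -1.37 were higher in ventral cells. Canonical Wnt targets had a median of -0.51, with Sp5 at -3.79 higher in ventral and Lgr5 at 5.59 and Tcf7 at 1.15 higher in dorsal cells. Retinoic acid genes had a median of -0.36. The degrading enzymes Cyp26a1 at -4.57 and Cyp26b1 at -1.43 and the synthesising enzyme Aldh1a1 at -1.70 were higher in ventral cells, and the binding protein gene Crabp2 at 1.68 in dorsal cells. Semaphorins and plexins divided 3 to 3, with a median of 0.07 that became -0.04 with TMM scaling and -0.11 with each class at its mean share. Sema3a at 1.18 and Nrp2 at 1.48 were higher in dorsal cells and Sema3f at -1.39 in ventral cells.

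Lists for other cell types were included because the pools could hold such cells. Mesothelial genes had a median of -1.48, with 8 of 10 members at least 2-fold higher in ventral cells, among them Muc16 at -3.36, Lrrn4 at -2.41 and Msln at -1.70, whereas Wt1 was at 0.10. Macrophage genes had a median of 0.84, with Mrc1 at 1.81 as the member at least 2-fold higher in dorsal cells, and a median of -0.54 with each class at its mean share. Endothelial genes had a median of -0.02, with 0 of 10 members 2-fold apart, and Emcn stood at -0.56 and Kdr at 0.82. Interferon genes had a median of 0.37 at the 98.7 percentile, with Irf7 at 1.15.

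Stress and metabolic genes were higher in dorsal cells. Dissociation and immediate early genes had a median of 0.90, with Nr4a1 at 2.32, Atf3 at 2.16, Jun at 1.87, Zfp36 at 1.59 and Egr1 at 1.47 among 5 of 12 members at least 2-fold higher in dorsal cells and 0 in ventral cells. Glycolysis and hypoxia genes had a median of 1.0, with 7 of 13 at least 2-fold higher in dorsal cells, including Car9 at 1.76, Pdk1 at 1.75, Bnip3 at 1.45 and Vegfa at 1.24. An NF-kB and cytokine list written after the dorsal chemokines had been seen had a median of 2.44, with 19 of 24 members at least 2-fold higher in dorsal cells. Among them were Ptgs2 at 3.42, Cxcl1 at 3.07 (2230 against 266 CPM), Il6 at 2.5 and Saa3 at 2.43.

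**Figure D3:**
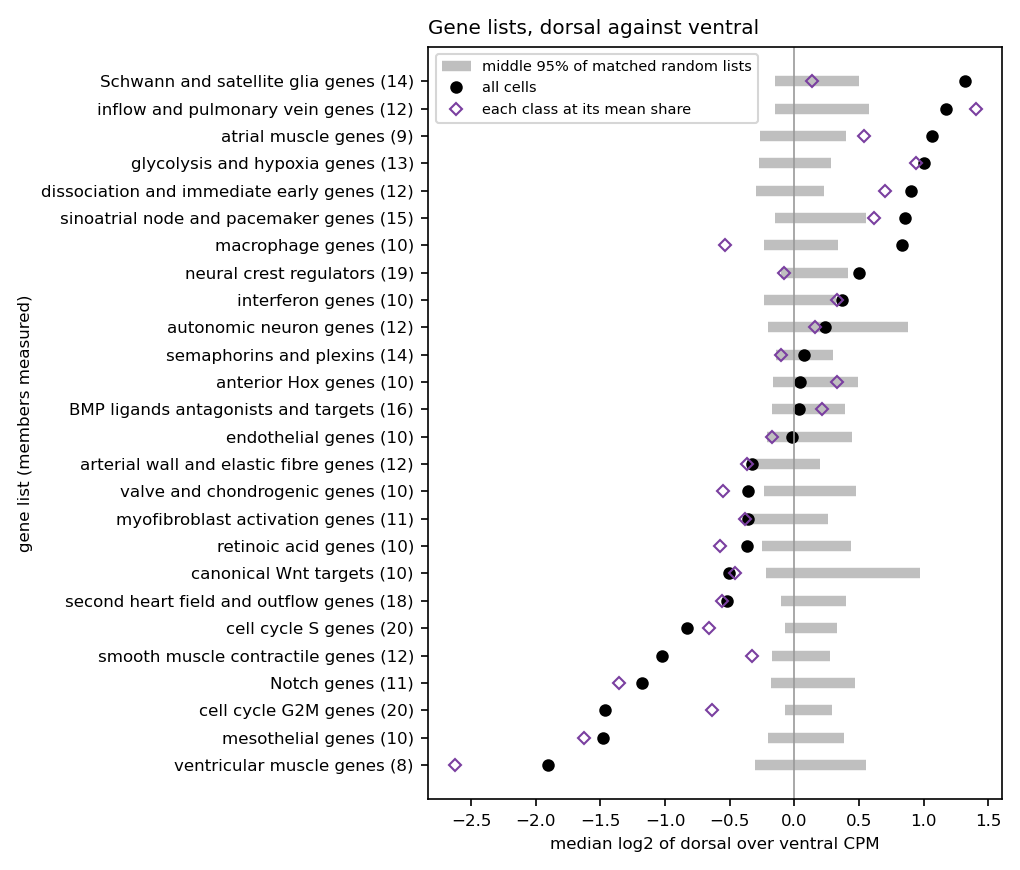
Median log2 ratio of dorsal to ventral CPM (x axis) for each of the 26 lists fixed in advance, over all cells (black) and with each class at its mean share (open diamonds), against the middle 95% of matched random lists (grey). Schwann and satellite glia genes stand at 1.32 over all cells and 0.14 at mean class shares, and ventricular muscle genes at -1.91 and -2.63.

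The third comparison repeated the sums within 4 classes with at least 100 cells in each library. In fibroblast-like cells, list medians were -1.40 for smooth muscle contractile, 1.22 for sinoatrial and 1.65 for inflow genes. Tbx20 stood at 1.23 CPM in dorsal and 61.5 CPM in ventral fibroblast-like cells, a log2 ratio of -5.64 (-5.92 to -5.37). Ccl17 at -5.43, Map2 at -4.89, the cardiac troponin Tnnt2 at -4.76, Scel at -4.63 and Sorbs2 at -4.40 followed. On the dorsal side were the chitinase-like protein Chil1 at 8.02 (7.30 to 8.86), Calca at 7.22, the interferon-induced chemokine Cxcl10 at 6.77, Csf3 at 6.14, Grem1 at 5.84 and Tnfsf8 at 5.65. Among list members, Gata4 at -3.72 and Nkx2-5 at -4.63 were higher in ventral cells and Tbx4 at 5.84, Foxf1 at 3.42, Tbx3 at 3.02 and Tbx5 at 2.90 in dorsal cells. At least 2-fold differences were found for 290 genes higher in dorsal and 315 higher in ventral cells, for 245 and 388 with TMM scaling, and for 263 and 274 when clusters 0 and 3 were added. Since the cells came from separate clusters, these values include differences between kinds of fibroblast-like cell.

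Mural-like cells came from dorsal clusters 10 and 12 and ventral clusters 17 and 23. Higher in dorsal cells were Sbspon at 10.24 (531 against 1 UMI, 7.75 to 15.54), the muscarinic receptor gene Chrm2 at 7.81, the G protein regulator Rgs2 at 6.31, Tnnt3 at 6.22, Tnfsf8 at 6.05 and Pdlim4 at 5.57. The intermediate filament gene Des stood at 893 against 36.8 CPM. Sbspon, Chrm2, Rgs2, Tnnt3 and Des were leading genes of cluster 12, with 108 dorsal cells, and not of the larger cluster 10. Values of mural-like cells thus include differences between kinds of mural-like cell. Higher in ventral cells were Rhox5 at -5.90, Gpx3 at -5.10, Tmem37 at -5.04, Acan at -4.88, Adamtsl2 at -4.33 and the collagen Col11a1 at -4.30. The Notch receptor gene Notch3 stood at -2.67. In all, 280 genes were at least 2-fold higher in dorsal and 276 in ventral mural-like cells, and 227 and 378 with TMM scaling. Smooth muscle contractile genes, lower in dorsal fibroblast-like cells with a median of -1.40, had a median of 0.29 in mural-like cells.

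Mesothelial-like cells came from dorsal cluster 7 and ventral clusters 13 and 15, and cell cycle genes led cluster 13. Sparcl1 at 6.87, the keratinocyte adhesion protein Cdsn at 6.63, Cxcl2 at 5.87, Ndufa4l2 at 5.61, the B cell chemokine Cxcl13 at 5.44 and Plac8 at 5.43 were higher in dorsal cells. S100a4 at -5.38, the keratin Krt14 at -5.07, Smpd3 at -4.76, Angptl7 at -4.19, the ribonucleotide reductase subunit Rrm2 at -3.89 and Nnat at -3.89 were higher in ventral cells. Uroplakin genes were also higher in ventral mesothelial-like cells, with Upk1b at 43.0 against 391 CPM. Of 10 mesothelial genes, 8 were at least 2-fold higher in ventral and 0 in dorsal cells of this class, with a median of -1.65. At Leiden resolution 2.0 a cluster of 438 dorsal cells led by Calca, Saa3 and Col6a5, also leading genes of cluster 7, took the fibroblast name. The values of this class therefore include differences between kinds of cell. All 20 G2 and M phase genes were at least 2-fold higher in ventral mesothelial-like cells, but 0 were with 4000 variable genes or without doublet removal, where more dorsal cycling cells took the mesothelial name. Counts at least 2-fold apart were 310 genes for dorsal and 379 for ventral cells.

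Glial-like cells of both libraries shared cluster 4, with 409 dorsal and 167 ventral cells. Of 6 autonomic neuron genes with UMIs in both libraries, 4 were at least 2-fold higher in dorsal and 0 in ventral cells, with a median of 2.60. List members with 0 UMIs in 1 library, such as Prph, were not among the 6. Prph, a peripheral neuron intermediate filament, had 229 dorsal and 0 ventral UMIs, at least 35.6-fold higher, and the stathmin Stmn3 had 150 and 0, at least 23.3-fold higher. Stmn2 had 378 and 2 UMIs, a log2 ratio of 6.46 (4.60 to 9.51). Gzmb with 285 and 0 UMIs, Snhg11 with 178 and 0, and Rgcc at 6.77 were also higher in dorsal cells. No cluster took the neuron name, and the cells with UMIs of neuron genes were not counted. The sums therefore do not show whether glial-like cells in general or a few neurons in cluster 4 carried these genes. Wfdc18 at -3.79, the myosin light chain Myl9 at -3.61, Acsbg1 at -3.52, Adam12 at -3.46 and Tagln at -3.27 were higher in ventral cells. Schwann and satellite glia genes had a median of 0.10 in this class and moved in both directions, with 3 of 14 members at least 2-fold higher in dorsal cells, Gap43 at 2.77, Gfra3 at 2.53 and Sostdc1 at 1.49, and 2 in ventral cells. In all, 198 genes were at least 2-fold higher in dorsal and 160 in ventral cells, and 150 and 197 with TMM scaling, so that the side with more genes turned over.

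Classes with at least 25 cells in each library were added after seeing the data. Arg1 stood at 1300 CPM in dorsal and 1.54 CPM in ventral macrophage-like cells, a log2 ratio of 9.72 (8.37 to 11.60). The interferon-induced genes Rsad2 at -4.96, Cmpk2 at -4.50 and Ifit1 at -4.38 and the chemokine Ccl5 at -3.75 were higher in ventral macrophage-like cells. In all, 236 genes were at least 2-fold higher in dorsal and 127 in ventral macrophage-like cells, and the latter count was 200 with a mitochondrial limit of 10%. Scrublet was run again for that setting, which held 115 ventral macrophage-like cells against 99. Cardiomyocyte-like cells showed Nppa at 3.24 and Myl7 at 1.93 on the dorsal and Myl2 at -6.65 and Myl3 at -4.66 on the ventral side, from 36 and 30 cells, with 424 and 438 genes at least 2-fold apart, and 485 and 406 with TMM scaling. Endothelial-like cells showed Csf3 at 7.41, Cxcl2 at 6.23 and Cenpf at 6.78 on the dorsal side and Dkk2 at -4.63, Ankrd1 at -4.37 and Sp5 at -4.23 on the ventral side, with 464 and 263 genes at least 2-fold apart.

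The fourth comparison concerned Isl1 (ENSMUSG00000042258, mm10 chromosome 13, 116298281 to 116309689, minus strand). Isl1 UMIs were rare in both domains and most frequent in skeletal muscle-like cells. At equal depth, 1.22% of dorsal cells (0.99 to 1.49) and 1.34% of ventral cells (1.12 to 1.59) had an Isl1 UMI. As counted, the shares were 2.47% (204 of 8273) and 2.78% (275 of 9882), and thinning left out 328 and 348 cells. The summed level was 1.18 CPM in dorsal and 1.47 CPM in ventral cells, a log2 ratio of -0.32 (-0.57 to -0.08). Barcodes with at most 100 UMIs, taken as free RNA, had Isl1 at the like levels of 1.08 CPM (4 UMIs) and 1.14 CPM (8 UMIs), and free RNA was not removed from the summed level or the shares. Macrophage-like cells, which should lack Isl1, had 0 of 148 dorsal and 1 of 99 ventral cells with a UMI, at median depths of 37939 and 25067 UMIs.

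Detection differed between classes and clusters. In skeletal muscle-like cells 19 of 35 (54.3%) had an Isl1 UMI, and 7 of 35 (20%, 8.44 to 36.9) after thinning, at a median depth of 35454 UMIs. The dorsal thinned share without them was 1.14%. Mesothelial-like cells had shares of 6.54% and 3.78% as counted and 2.66% and 2.34% after thinning, for dorsal and ventral. Glial-like cells had an Isl1 UMI in 10 of 409 dorsal cells and in 0 of 167 ventral cells, at median depths of 12705 and 16447 UMIs, which at this depth does not show that Isl1 was absent from them. Any neurons within this cluster were not set apart. Cardiomyocyte-like cells had it in 0 of 36 dorsal and 4 of 30 ventral cells. Among ventral fibroblast-like clusters, cluster 20, led by Cd200 and Cxcl12 and holding Eln and Fbln5 among its leading genes, had a thinned share of 3.32% (2.48 to 4.34) and 41.8% of all ventral Isl1-positive cells. Cluster 16 had 0.109% (0.0132 to 0.394). Within fibroblast-like cells Isl1 stood at 0.834 CPM in dorsal and 1.51 CPM in ventral cells, a log2 ratio of -0.86 (-1.25 to -0.48), and within mesothelial-like cells at 2.59 and 1.51 CPM, a ratio of 0.78 (0.20 to 1.38).

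**Figure D4:**
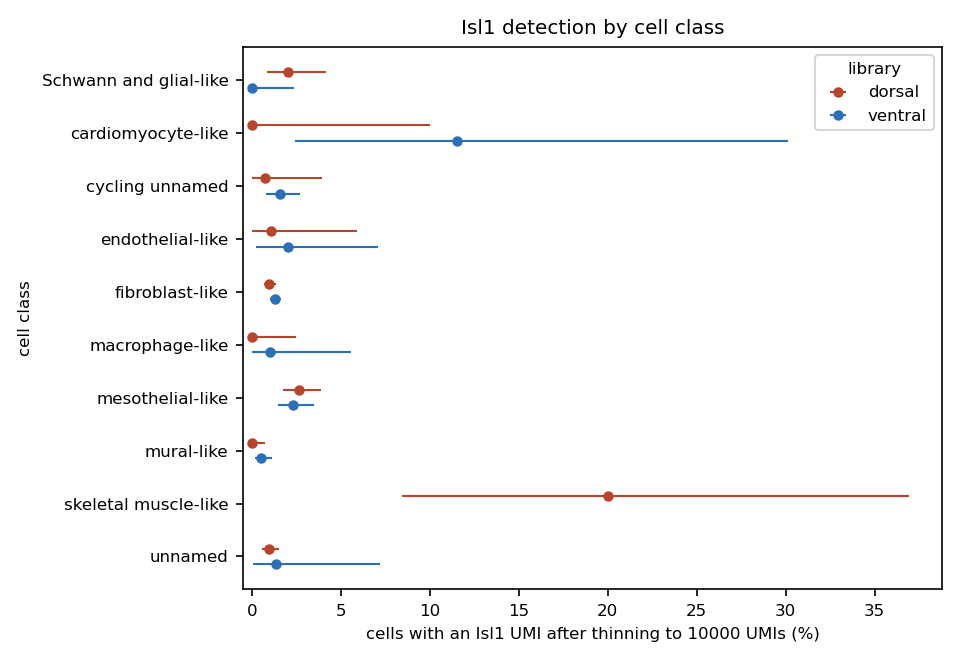
Share of cells with an Isl1 UMI after thinning to 10000 UMIs (x axis, %) by cell class and library, with bars for 95% Clopper-Pearson intervals (counting error only). Skeletal muscle-like cells of the dorsal library reached 20%, against 1.22% of all dorsal and 1.34% of all ventral cells.

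Cells with an Isl1 UMI were set against the rest of their library to ask which genes went with Isl1. Most of the leading genes of Isl1-positive cells in both libraries were striated muscle genes. The lists for chamber muscle did not follow them, with dorsal and ventral medians of -0.03 and -0.29 for atrial and -0.27 and 0.06 for ventricular muscle genes. Autonomic neuron genes had the highest dorsal list median, at 1.09 (0.50 to 1.63), with 0.27 (0.10 to 0.42) in ventral cells, over 5 measured members. Endothelial genes had 0.60 and 0.61 and macrophage genes -4.75 and -1.58. The log2 ratios in dorsal and ventral cells were 2.90 and 2.96 for Mlip, 2.46 and 2.81 for the muscle LIM protein Csrp3, 4.59 and 2.19 for the slow troponin Tnni1 and 4.56 and 1.97 for Tnnc1. The titin gene Ttn (4.04 and 1.95), Actn2 (4.35 and 1.80), Ckm (4.62 and 1.72), Smpx (3.70 and 1.92), Trdn (2.70 and 1.86) and Cox6a2 (2.02 and 2.10) were also higher in Isl1-positive cells. Skeletal muscle-like cells made up 9.31% of the 204 dorsal Isl1-positive cells and 0.198% of the rest. Cardiomyocyte-like cells made up 0% of the dorsal Isl1-positive cells. In the ventral library they made up 1.45% of the 275 Isl1-positive cells and 0.271% of the rest, with 0% skeletal muscle-like cells. Different muscle-like cells thus entered the 2 sides, so the shared genes do not show a muscle programme in Isl1-positive cells at large. Outside muscle, the neuropeptide gene Nts stood at 1.99 and 2.02 and Ppp1r14c at 2.03 and 1.97. In all, 28 genes were at least 2-fold higher in Isl1-positive cells of both libraries, and 11 were without skeletal muscle-like and cardiomyocyte-like cells, an alternative added after seeing the data.

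Lower in Isl1-positive cells of both libraries were the macrophage lysozyme Lyz2 (-4.59 and -1.82), Hp (-1.55 and -2.83), Gpx3 (-1.24 and -2.71), Gucy1a3 (-2.70 and -1.20), Ifi27l2a (-1.44 and -1.70) and the lipase Lpl (-1.07 and -1.19). Some list members were higher in Isl1-positive cells of 1 library. In dorsal cells these were the myogenic factor Myog at 5.39 and Tbx1 at 2.86. In ventral cells they were the cardiac factor Nkx2-5 at 2.34, the proliferation gene Mki67 at 1.19 and Sema3c at 1.19. Muscle-like cells were not left out of these values. Of the sinoatrial genes, Shox2 stood at -1.40 and -1.85, Tbx18 at -1.08 and -0.75 and Tbx3 at 0.63 and -0.28, and Hcn4 had 1 and 3 UMIs in Isl1-positive cells. The glial factor Sox10 stood at -0.05 in dorsal and -4.22 in ventral cells, the latter from 1 UMI.

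The fifth comparison counted cycling cells. After thinning, 3.84% of dorsal cells (3.43 to 4.28) and 12.2% of ventral cells (11.5 to 12.9) had at least 3 UMIs over G2 and M phase genes, a log2 ratio of -1.67 (-1.85 to -1.49). Mesothelial-like cells had 2.25% in dorsal and 23.1% in ventral cells, a log2 ratio of -3.36 that depended on which cycling cluster took the mesothelial name. With 4000 variable genes, a clustering added here after seeing the data, that cluster held 138 dorsal and 118 ventral cells, and the shares were 13.4% and 23.3%, a log2 ratio of -0.80. Without doublet removal they were 15.1% and 23.4%, a log2 ratio of -0.64. Macrophage-like cells had 28.4% and 39.8%, fibroblast-like cells 1.09% and 2.09%, and mural-like cells 0.583% and 2.5%. The fibroblast-like and mural-like shares leave out the unnamed cycling cluster, which held 139 of the 305 dorsal and 726 of the 1163 ventral cycling cells and carried fibroblast and mural markers, so they do not show how often cells of these classes cycled. Endothelial-like cells went the other way, at 7.61% and 1.01%, from 7 and 1 cells, and glial-like cells had 5.56% and 7.74%. All 20 cell cycle G2M genes were at least 2-fold higher in ventral cells, with a list median of -1.46 that was -0.64 with each class at its mean share. Examples were Nusap1 at -1.76, Hmmr at -1.75, Ube2c at -1.64 and Birc5 at -1.61. Cell cycle S genes had a median of -0.83, with 6 of 20 members at least 2-fold higher in ventral cells, among them Rrm2 at -1.80 and Uhrf1 at -1.67. Without thinning the shares were 10.0% and 17.8%, a log2 ratio of -0.82, and free RNA was not removed from these counts.

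**Figure D5:**
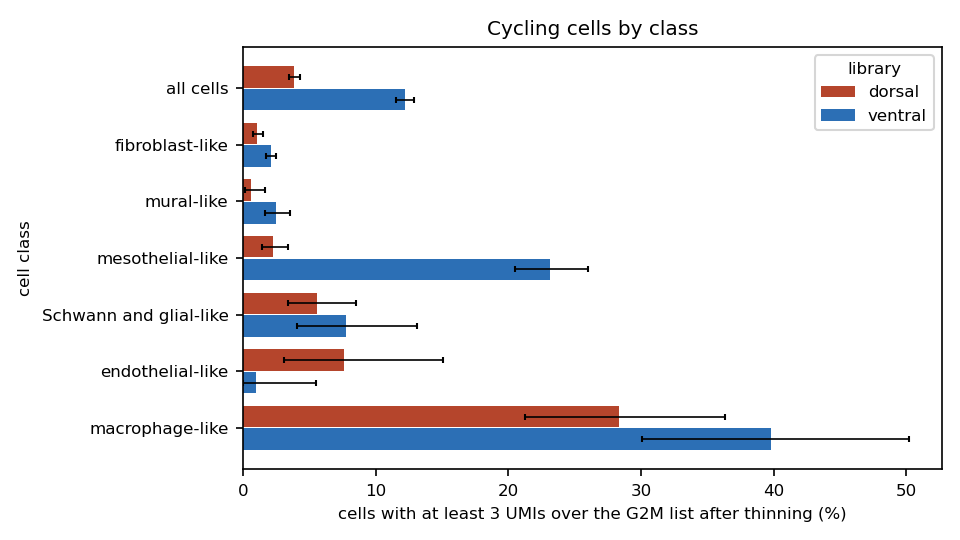
Share of cells with at least 3 UMIs over the G2M list after thinning to 10000 UMIs (x axis, %), for all cells and for 6 classes of each library, with bars for 95% Clopper-Pearson intervals (counting error only). All dorsal cells stand at 3.84% and all ventral cells at 12.2%. The bars of mesothelial-like cells hold for the main clustering.

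The last comparison asked whether both pools held the sexes in the same ratio, from Xist, which is transcribed from the inactive X chromosome, and from Y-linked genes. Among cells with UMIs of 1 kind, 52.8% of dorsal cells (51.7 to 54.0) and 61.2% of ventral cells (60.2 to 62.2) had Xist. Both kinds were found in 10.2% of dorsal and 6.26% of ventral cells. Xist UMIs outnumbered Y-linked UMIs 4.48-fold in dorsal and 4.65-fold in ventral cells, a log2 ratio of -0.05 (-0.09 to -0.02) between the domains, which was -0.22 with each class at its mean share.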

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

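Of the tests below, those of a library-wide technical difference, of free RNA as the source of Isl1 and of airway or foregut tissue were chosen only after the results had been seen.

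The median log2 ratio of Isl1-positive cells to the rest had opposite signs in the dorsal and ventral libraries, with both 95% counting intervals clear of 0, for 5 gene lists. A further 4 lists had opposite signs with an interval that held 0 in at least 1 library. These differences between domains were not tested. Values for dorsal and ventral cells were -0.27 and 0.21 for second heart field and outflow genes, -1.16 and 0.11 for smooth muscle contractile genes, -0.17 and 0.11 for cell cycle S genes, -0.91 and 1.19 for cell cycle G2M genes, and 0.12 and -0.21 for interferon genes. Barcodes with over 100 and fewer than 500 UMIs, which enter no comparison, numbered 65440 in the dorsal and 8544 in the ventral library. They held 3.96% of dorsal and 0.512% of ventral UMIs, of which 5.47% and 14.3% were mitochondrial. Across genes, their log CPM correlated with that of the called cells of the same library at r = 0.981 and 0.971, over genes that are not independent replicates.

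Dorsal and ventral mesenchymal cells lay in separate clusters. A difference in depth is argued against because, after thinning every cell to 10000 UMIs and clustering again, 92.6% of fibroblast-like and unnamed cells still lay in clusters with at least 90% of cells from 1 library. A technical difference acting alike on all cells is argued against as the whole cause. The evidence is the share of neighbours from the other library, relative to full mixing. This share was 0.363 in endothelial-like and 0.416 in macrophage-like cells, against 0.0125 in fibroblast-like cells. Fibroblast-like samples drawn at the sizes of the other classes gave 0.0101 to 0.10. Mesothelial-like and mural-like samples so drawn reached 0.137 and 0.0974. Glial-like cells, at 0.171, did not stand apart, with 0.193 in unnamed cells and 0.138 in the unnamed cycling cluster. The argument therefore rests on endothelial-like and macrophage-like cells. All of these values were below 1. Endothelial-like and macrophage-like cells also differed between libraries, with NF-kB and cytokine list medians of 1.58 and 1.36, higher in dorsal cells. An effect of library or culture on mesenchymal cells in particular, or a partial one on all cells, therefore stays open. A difference between the dissected domains stays open too, as untested, because domain and library were confounded.

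Inflammatory genes such as Cxcl1, Il6 and Saa3 were higher in dorsal cells. Free RNA from a few producing cells is argued against as the whole cause, since the median ratio of dorsal fibroblast-like CPM to CPM in barcodes with at most 100 UMIs was 1.31 over the NF-kB and cytokine list. An acute response to dissociation cannot be told apart from other causes, because the immediate early list was higher in dorsal cells of every class tested, with a lowest class median of 0.32 and a second lowest of 0.41, between the bounds set in advance. The NF-kB and cytokine list was itself higher in dorsal cells of every named class with at least 25 cells in each library. Its class medians ran from 1.32 in mural-like to 2.49 in fibroblast-like cells. A library-wide effect, a response to the 5 days of culture and a difference between the domains themselves stay open, as untested.

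Isl1 UMIs were most frequent in skeletal muscle-like cells of the dorsal library. Free RNA is argued against, since the lower bound of their thinned share was 7.42 times the share in the other dorsal cells. Striated muscle around the airways or foregut is a candidate source of these cells, and cells with a UMI of Tbx4, Barx1 or Nkx6-1, taken as genes of airway and foregut mesenchyme, were 26.9 times as frequent in dorsal as in ventral cells after thinning (14.4% against 0.535%, with 2.03% of dorsal macrophage-like cells). That test decides nothing, because Barx1 and Nkx6-1 were picked after they had been seen among the leading genes of dorsal clusters, and Tbx4 belongs to the inflow list. The epithelial gene Epcam was low in the summed cells, at 1.36 CPM in dorsal and 0.525 CPM in ventral cells. Its UMIs lay in few cells, 277 in 22 dorsal and 117 in 9 ventral cells. Among list members with too few UMIs to be measured, Nkx2-1 had 20 UMIs in 7 dorsal cells and 0 in ventral cells. Scgb1a1 had 32 UMIs in 5 dorsal cells and 1 in a ventral cell. Sftpc had 0 dorsal UMIs and 1 ventral UMI, and Krt5 had 0 in both. All 4 measured epithelium genes were at least 2-fold higher in dorsal cells, with a list median inside the middle 95% of random lists. Whether the skeletal muscle-like cells came from the same tissue as these epithelial UMIs was not tested. Their tissue of origin therefore cannot be told apart from other sources of muscle or from the domain itself.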

How the results depend on the processing

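The alternatives with an equal doublet share in both libraries, without muscle-like cells, with classes of at least 25 cells, with large unnamed clusters counted as fibroblast-like, and with other clusterings for cycling cells were chosen after seeing the data. No paired analysis was possible because each domain had 1 pooled library. For main results, 138 alternatives kept direction and size, 24 moved beyond the counting interval or by over 1.5 times, and 3 turned over. For the remaining results, mostly list medians and named genes, 267 kept, 122 moved and 5 turned over. The cause was not tested except where the construction of the alternative shows it.

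Class shares depended on the clustering and on the cells kept. Scrublet was run again with the minimum of 2000 UMIs and with the mitochondrial limit of 10%. Shifts under these settings therefore mix the limit with the doublets removed. The log2 ratio of fibroblast-like shares was 0.12 with the unnamed clusters added, -0.63 with a minimum of 2000 UMIs, -0.39 with a mitochondrial limit of 10%, -0.54 without doublet removal, and -0.37 and -0.0678 at Leiden resolutions 0.5 and 2.0. Mural-like shares in the same order of settings, leaving out the unnamed clusters, gave -0.32, -1.29, -1.45, -0.52 and -0.63, then -1.06 with equal doublet shares and -1.50 with 4000 variable genes. A cluster led by cell cycle genes took the mural name without doublet removal (20 dorsal and 913 ventral cells) and with 4000 variable genes (16 and 778). Mesothelial-like shares gave -0.56 at resolution 2.0 and 0.48 with 4000 variable genes. Cardiomyocyte-like shares gave 1.41 with the mitochondrial limit of 10%, which left 16 ventral cells, too few for sums within that class. Skeletal muscle-like cells numbered 31 to 38 in the dorsal and 0 in the ventral library under every clustering run.

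Without an expression minimum, 4445 genes were at least 2-fold higher in dorsal and 2153 in ventral cells, since genes with few counts then entered. With each class at its mean share, medians were -0.0830 for neural crest regulators, 0.62 for sinoatrial genes, -0.11 for semaphorins and plexins and -0.54 for macrophage genes, and the Xist to Y-linked log2 ratio was -0.22. The construction takes out differences in class shares. It also drops skeletal muscle-like cells and takes the unnamed clusters as 1 class, so class shares alone are not shown as the cause. TMM scaling gave -0.0437 for semaphorins and plexins and -0.0736 for anterior Hox genes. Without muscle-like cells the atrial median was -0.0387, and 11 genes were at least 2-fold higher in Isl1-positive cells of both libraries. Isl1 shares for dorsal and ventral cells were 2.47% and 2.78% without thinning and 0.109% and 0.152% after thinning to 1000 UMIs, as depth sets how many cells show a rare transcript. Without thinning the log2 ratio of cycling shares was -0.82. In mesothelial-like cells it was -0.80 with 4000 variable genes, -0.64 without doublet removal and -2.71 at resolution 2.0. Depth limits Isl1 and other rare regulators to a few UMIs per class.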

Other observations

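Cells of different sexes came from different animals of the same pools, which gave a comparison within each library that was added after seeing the data. Cells with Xist but no Y-linked UMIs and cells with Y-linked but no Xist UMIs were summed separately. All 276 dorsal-high and all 295 ventral-high genes had the same direction in both sums, although they had been picked from the pooled values. At least 2-fold differences held in both sums for 256 and 271 of them. Across 5808 genes the log2 ratios of the sums correlated at r = 0.979, over genes that are not independent replicates. Arg1 stood at 10.21 in cells with Xist and 11.55 in cells with Y-linked UMIs, Grem1 at 5.17 and 5.75, Cxcl2 at 4.64 and 4.90, Ccl17 at -4.67 and -5.18 and Acan at -4.88 and -4.31. Both sums shared the same culture and library, so they give no replicate of the domain comparison.

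Genes of airway and foregut mesenchyme and of airway and foregut epithelium formed lists that were added after seeing the data. All 3 mesenchyme genes (median log2 ratio 5.23) and all 4 measured epithelium genes (median 1.62, at the 93.8 percentile of random lists) were at least 2-fold higher in dorsal cells. Barx1 stood at 11.03 against 0.503 CPM and Nkx6-1 at 3.54 against 0.0943 CPM.

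Dorsal mural-like cells held a distinct group of 108 cells, cluster 12, with 0 ventral cells, led by Des, Actg2, Sbspon, Myh11 and Chrm2. The other dorsal mural-like cluster, with 442 dorsal and 29 ventral cells, was led by Cxcl15, Itih4 and Rgs5. UMIs of both sexes were found in 26.4% of dorsal macrophage-like cells (39 of 148, median depth 37939 UMIs) and in 9.48% of dorsal fibroblast-like cells (median depth 22261 UMIs). Of 35 skeletal muscle-like cells, 6 had UMIs of both sexes.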
